A study of Mus musculus with 8 samples.

How the data were processed

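RNA sequencing was carried out on germinal centre precursor B cells (pre-GC B cells) sorted from mouse spleen on day 9 of infection with a non-lethal strain of Plasmodium yoelii, a rodent malaria parasite. Per the labels' protocols, the cells were gated as positive for B220, CD38 and GL7 and negative for IgD, total RNA came from 100000 sorted cells, and libraries were made with a stranded mRNA kit. The series holds 8 libraries, 4 from mice whose floxed Tbk1 alleles were exposed to Mb1-Cre (Tbk1-deficient) and 4 from mice with the same floxed alleles and no Cre (wild-type). The labels do not say whether each library came from a separate animal, so the p-values measure the spread between these libraries.

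The deposited values were FPKM (fragments normalized to transcript length and library size), computed by the authors, in 1 table of 24346 genes by 8 libraries. The submitters' processing notes name TopHat2 2.0.13, Bowtie2 2.2.3, SAMtools 0.1.19, Cufflinks 2.2.1 and the mouse genome build mm10, without saying which options were set; the annotation and the strand setting used for counting were not given in the sources used here. Genes that overlap another gene on either strand are therefore uncertain, as are families of near-identical copies such as the globins and the replication histones. All 8 columns were matched to their libraries by name, and no 2 libraries shared more than 0.273% identical values among the tested genes. Immunoglobulin constant and variable genes were not analysed here.

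FPKM is not a count, so no count test was used. Values were taken as log2(FPKM + 1), and a fold change is on that scale, which understates the change of genes with low values. Genes with a mean of at least 1 FPKM over all 8 libraries were tested (9905 genes). Groups were compared with limma 3.58.1 in R 4.3.3, with an intensity trend in the empirical Bayes step and genotype as the only term, and p-values were adjusted by the Benjamini-Hochberg method with a threshold of 0.05. An SE is limma's moderated standard error, and intervals are 95% confidence intervals. Tbk1 and Cd79a were also compared by an exact two-sided permutation test over all 70 assignments of the libraries. Before the data were examined, 34 gene lists were fixed, covering B cell states, signalling, metabolism, stress, cell cycle and markers of other cell types. The 28 lists with at least 5 tested genes, other than the sex-linked genes, were tested with camera at its preset correlation of 0.01, with camera at an estimated correlation, and with fry. Members of each list were also counted with p-values adjusted over the list alone.

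The genes named in the text followed a rule fixed at the same time. It took Tbk1 and Cd79a; the 12 highest and 12 lowest fold changes among changed genes whose 4 Tbk1-deficient values all lay on one side of the 4 wild-type values, without small RNA and unnamed genes (1 changed gene, Snora81, was left out in this way); the leading members of each list; and 12 B cell genes whatever their values. Genes named outside the rule are marked as such. Gene positions and overlaps came from GENCODE release M21 on GRCm38, the assembly that mm10 denotes, and 96.1% of the tested genes had an annotation under their symbol.

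Depth was not given in the sources used here. Low FPKM values rise in whole-fragment steps, and the ratio of a gene's values to those in wild-type library 1 came out as a ratio of small whole numbers, within 0.01 on the log2 scale, for 68.9% to 72.5% of low values against 8.9% by chance. From these steps the relative depth of the libraries ranged from 0.849 to 1.00 of that of wild-type library 1. Single-transcript genes (59 of them) put that library at about 13000000 fragments (quartiles 12700000 and 13300000), an approximate figure. The procedure was tested on simulated data made from these libraries. With 200 of the 9905 genes changed, limma recovered 69.5% of changes of 0.5 on the log2 scale with 3 false calls. It recovered 96.5% of changes of 1 with 6 false calls. Camera called a list shifted by 0.2 and 0 of the other lists among the 28. The simulated genes varied independently of each other, whereas the estimated correlation within the real lists reached 0.85 (ribosomal proteins). The simulation therefore cannot show how often camera falsely calls lists of correlated genes.

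The alternatives fixed beforehand were pseudocounts of 0.1 and 0.25, no filter, a filter at a mean of 5 FPKM, median-ratio scaling, quantile normalization, rescaling every library to the same sum, no intensity trend, a robust variance step, array weights, the replicate number as a block, and leaving out each library in turn. A term for sex, the male libraries alone, and leaving out transcripts under 300 nt were added after seeing the data. Sex was read from Xist and the Y-linked genes Ddx3y, Eif2s3y, Kdm5d and Uty.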

Results

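The transcriptome of splenic pre-GC B cells, the activated cells that precede germinal centre B cells, was measured on day 9 of Plasmodium yoelii infection. There were 4 Tbk1-deficient and 4 wild-type libraries. TBK1 is a kinase of innate immune sensing that also restrains non-canonical NF-κB signalling. About 11000000 to 13000000 fragments stood behind each library. Expression correlated between libraries with r from 0.978 to 0.990 across genes, with means of 0.985 within and 0.983 between genotypes. All 4 Tbk1-deficient libraries were male, whereas wild-type libraries 1 and 2 were female and wild-type libraries 3 and 4 male. As no Tbk1-deficient library was female, a term for sex and the male libraries alone give the same fold changes by design. These fold changes rest on wild-type libraries 3 and 4. Xist stood at 28.2 and 40.0 FPKM in the female libraries, where the 4 Y-linked genes were listed at 0.

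Tbk1 itself (chromosome 10, 121546455 to 121586787, GRCm38) stood at 13.5 ± 1.18 FPKM in the Tbk1-deficient libraries and 16.4 ± 2.25 in the wild-type libraries (SD, n = 4 each). Its log2 fold change was −0.26 ± 0.099 (SE), which did not pass the test (limma adjusted p = 0.328; exact permutation p = 0.0857, two-sided). The Tbk1-deficient values ran from 12.6 to 15.2 FPKM and the wild-type values from 14.3 to 19.2. A gene-level FPKM also takes in transcript parts outside the floxed segment, whose position was not given in the sources used here, so this value does not check the deletion. Cd79a (chromosome 7, 24897381 to 24902197) encodes the Igα chain of the B cell receptor, and its locus carries the Mb1-Cre insertion. It fell from 1048 ± 156 to 435 ± 27.5 FPKM (log2 fold change −1.26 ± 0.10 SE, limma adjusted p = 0.00070). The exact permutation p was 0.0286, the smallest that 4 libraries against 4 can give. Because Cre was present in the Tbk1-deficient group alone, loss of TBK1 and the Cre insertion cannot be separated in this design.

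**Figure D1:**
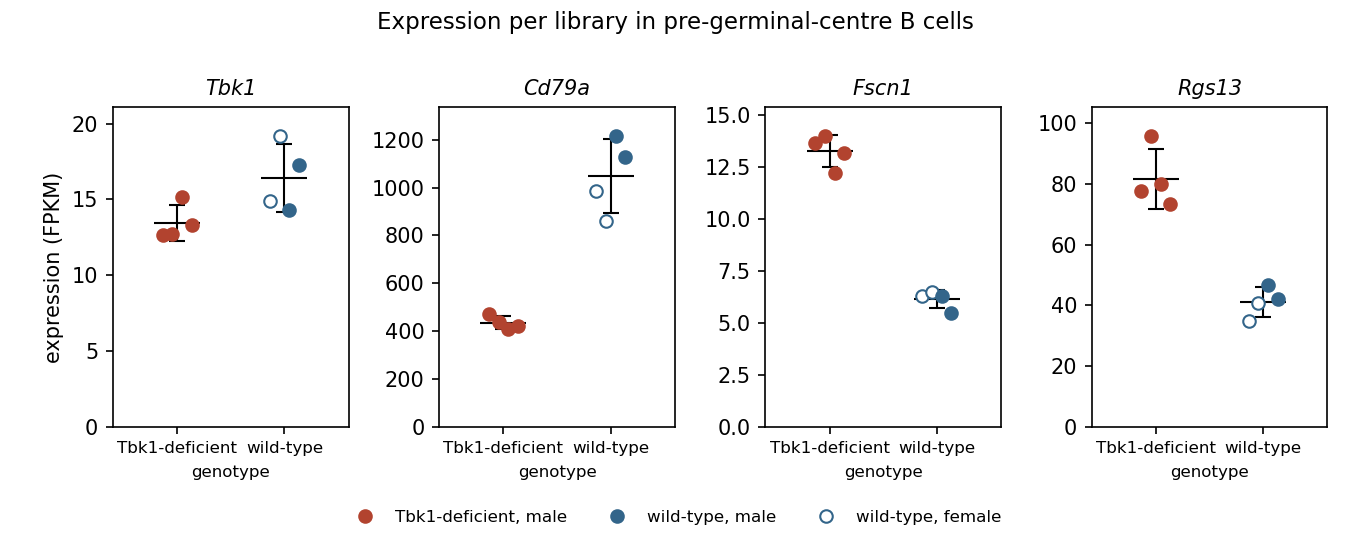
FPKM of Tbk1, Cd79a, Fscn1 and Rgs13 in each library, by genotype, with the mean (long bar) and SD (error bar) of 4 libraries and open points for female libraries. Tbk1 values overlap between the genotypes. The Tbk1-deficient Cd79a values (409 to 473 FPKM) lie below all 4 wild-type values, and the Fscn1 and Rgs13 values above.

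Beyond Cd79a, pre-GC B cells of the Tbk1-deficient group had more Fscn1, Rgs13, Trp73 and Il10 and less Ndrg1, Nrgn and Tsc22d3. Fscn1, an actin-bundling protein of activated and migrating cells, rose from 6.15 ± 0.448 to 13.3 ± 0.771 FPKM (log2 fold change 1.00 ± 0.075 SE, limma adjusted p = 0.00044). Rgs13, a regulator of chemokine receptor signalling typical of germinal centre B cells, rose from 41.1 ± 4.87 to 81.6 ± 9.77 FPKM (0.97 ± 0.10, limma adjusted p = 0.0038). Trp73, a relative of p53 that overlaps Trp73os on the other strand, rose from 1.65 ± 0.116 to 3.87 ± 0.325 FPKM (0.88 ± 0.090, limma adjusted p = 0.0038). Il10, an anti-inflammatory cytokine, rose from 3.91 ± 0.344 to 6.90 ± 1.03 FPKM (0.68 ± 0.10, limma adjusted p = 0.032). Means are given with SD, n = 4, and fold changes on the log2(FPKM + 1) scale. With a term for sex or with the male libraries alone, Il10 (0.63), Ndrg1 (−0.84) and Tsc22d3 (−0.49) no longer passed, with fold changes of about the same size. Nrgn (−0.86) did not pass with the male libraries alone.

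In all, 38 of 9905 genes changed, 24 higher and 14 lower in the Tbk1-deficient libraries, and 34 of the 38 moved by less than 1 on the log2 scale. The other named genes that rose were S100a10 (0.93), Chst1 (0.86; 1.51 with a pseudocount of 0.1), the decoy receptor Il1r2 (0.83; 1.63 with a pseudocount of 0.1), the lipase Mgll (0.78), Rap1gap2 (0.65) and Shisa8 (1.00). Nfkbid, an atypical inhibitor of NF-κB, rose by 0.77, and the short transcript Snhg9, which overlaps Rps2 on the other strand, by 1.49. Allowing for relative depth, the Snhg9 values of all libraries were small whole multiples of that in wild-type library 1 (5.22 FPKM). Its fold change may therefore rest on few fragments. Those that fell were Ndrg1 (−0.81), Nrgn (−0.81), Amn1 (−0.76), Pxdc1 (−0.68), Tm6sf1 (−0.61), Apol11b (−0.60), Serpinb6b (−0.59) and Rnf130 (−0.50). The glucocorticoid-induced gene Tsc22d3 fell by −0.58. The proton channel gene Hvcn1 (−0.47) and Tctn1 (−0.45) also fell; they overlap on opposite strands, so their values cannot be told apart with certainty. Snora81, a small RNA that overlaps Eif4a2 and was named here after its values were seen, was listed at 9.33, 21.6, 9.48 and 9.93 FPKM in the Tbk1-deficient libraries. It was listed at 0 in every wild-type library. Allowing for relative depth, its Tbk1-deficient values were small whole multiples of that in Tbk1-deficient library 1 (9.33 FPKM). This difference may therefore also rest on few fragments. At an unadjusted p under 0.05, 1126 genes differed, and in 741 genes (7.48%, against 2.86% by chance) the values of the genotypes did not overlap.

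The number of changed genes depended on single libraries. It was 5, 19, 20 and 6 without Tbk1-deficient libraries 1, 2, 3 and 4, and 6, 117, 15 and 6 without wild-type libraries 1, 2, 3 and 4. Cd79a, Fscn1, Rgs13 and Trp73 passed without any 1 library, while each of the other 20 named genes that changed was lost without at least 1. Those 20 passed in 1 to 6 of the 8 runs that left out a library, Il10 and Tsc22d3 in 2. With a term for sex 12 genes passed (9 of the 38), and with the male libraries alone 20 genes passed (10 of the 38). The number was 12 with no filter, 20 after rescaling every library to the same sum and 220 with array weights.

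**Figure D2:**
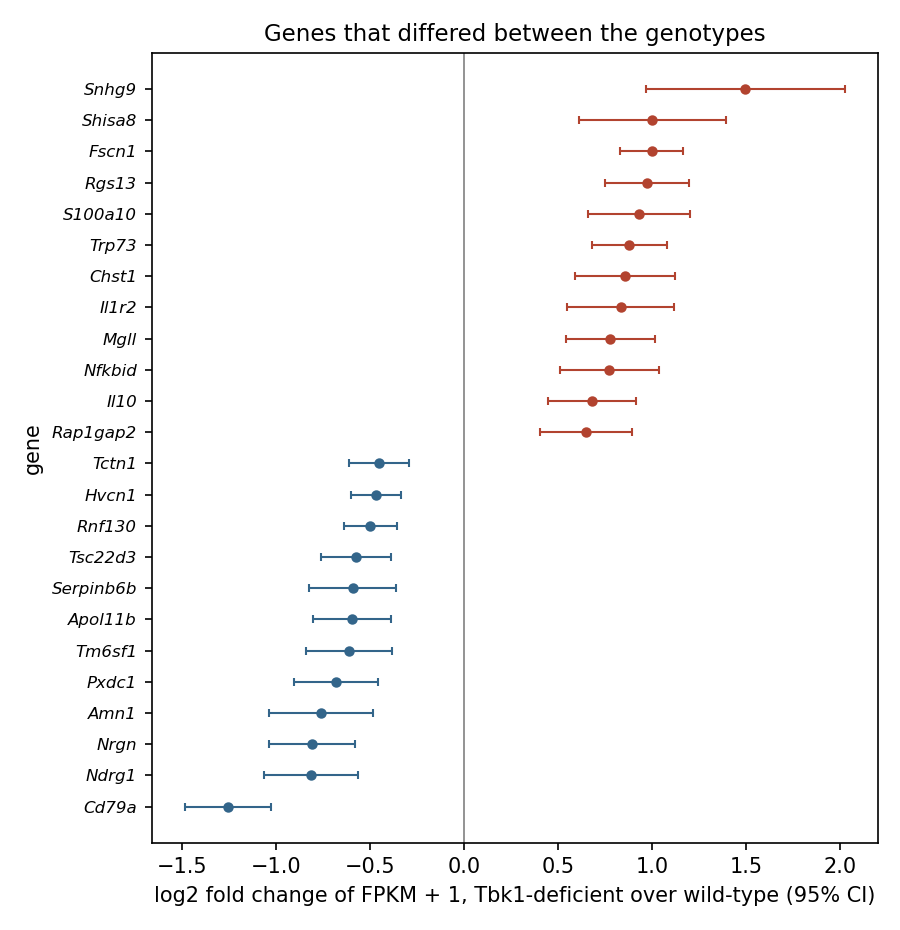
Log2 fold change of FPKM + 1 (Tbk1-deficient over wild-type) with limma's 95% confidence interval for the 24 named genes that changed, 4 libraries per genotype. Cd79a has the lowest value (−1.26) and Snhg9, a short transcript whose values may rest on few fragments, the highest (1.49).

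Of 12 B cell regulators fixed for reporting, 0 passed limma's test over all genes and 6 had an unadjusted p under 0.05. Irf4, which drives plasma cell differentiation, stood at 16.2 ± 0.556 against 11.4 ± 1.72 FPKM in wild type (log2 fold change 0.48, limma adjusted p = 0.067). Of the 22 alternatives Irf4 passed in 3, among them the male libraries alone (0.57, limma adjusted p = 0.028), and not in 19. Myc stood at 30.2 ± 3.42 against 22.1 ± 1.40 FPKM (0.43, limma adjusted p = 0.067). Prdm1 gave a log2 fold change of 0.42, Cd38 −0.33, Icosl −0.26, Foxo1 −0.12, Fas −0.11 and the germinal centre repressor Bcl6 −0.10. Bach2 (−0.05), Pax5 (−0.05) and Irf8 (0.01) lay close to 0 and changed sign with a term for sex (0.14, 0.08 and −0.01).

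Of the 28 gene lists tested, 12 were called with camera's preset correlation, 5 higher and 7 lower in the Tbk1-deficient libraries. Camera with an estimated correlation called 0, with 6 at an unadjusted p under 0.05, and fry called 6. The 12 lists hold 277 tested genes, of which 0 passed limma's test over all genes and 85 had an unadjusted p under 0.05. Beside each list described next, the erythroid markers were lower in the Tbk1-deficient libraries (median −0.28), the heat shock genes that respond to cell handling were higher (median 0.21), and 2 wild-type libraries were female.

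All 35 genes of MYC targets and ribosome biogenesis had positive log2 fold changes, with a median of 0.20 (camera adjusted p = 4.86e-19; adjusted p = 0.075 with an estimated correlation). Of these, 20 rose adjusted over the list alone, among them Myc (0.43) and the chaperonin gene Hspe1 (0.25). Plasma cell genes had a median of 0.27, with 20 of 23 positive (camera adjusted p = 1.30e-09; adjusted p = 0.075 with an estimated correlation). Adjusted over the list alone 11 rose, including Irf4 and Creld2 (0.35), a protein of the endoplasmic reticulum. Jchain, the 1 analysed gene of the immunoglobulin constant list, stood at 303 ± 5.48 against 249 ± 21.9 FPKM (0.28, limma adjusted p = 0.118). Heat shock genes, fixed as a marker of cell handling, had a median of 0.21, with 14 of 15 positive (camera adjusted p = 3.35e-05; adjusted p = 0.335 with an estimated correlation). In that list 2 rose adjusted over the list alone, the overlapping neighbours Hspe1 and Hspd1 (0.30); the median was 0.12 without Tbk1-deficient library 4 and 0.14 without wild-type library 4. ATF4 stress genes had a median of 0.13, with 18 of 20 positive (camera adjusted p = 8.00e-05; adjusted p = 0.275 with an estimated correlation). Of them 4 rose adjusted over the list alone; its leading genes were Mthfd2 (0.24) and Slc7a1 (0.24), and without Tbk1-deficient library 2 the median was 0.19. NF-κB targets had a median of 0.08, with 22 of 29 positive (camera adjusted p = 0.0018; adjusted p = 0.335 with an estimated correlation). There were 6 that rose adjusted over the list alone. The leading genes of the list were Bcl3 (0.52) and Tnfaip3 (0.35). Bcl3 lies within 10 Mb of Cd79a on chromosome 7, so for it DNA carried along with the Cre insertion cannot be told apart from other causes. The call on NF-κB targets was lost without Tbk1-deficient library 2 (median 0.05, adjusted p = 0.052) and with the male libraries alone (0.06, adjusted p = 0.051), within a range of 9.40e-05 to 0.335 over all alternatives.

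Type I interferon genes were lower, with 21 of 23 negative and a median of −0.14 (camera adjusted p = 5.09e-05; adjusted p = 0.148 with an estimated correlation). Adjusted over the list alone 2 fell; its leading genes were Irf9 (−0.39) and Cmpk2 (−0.48). With no filter the median was −0.06. B cell receptor signalling genes had a median of −0.08, with 24 of 32 negative (camera adjusted p = 8.00e-05; adjusted p = 0.075 with an estimated correlation). Adjusted over the list alone 4 fell; its leading genes were the inhibitory receptor gene Cd72 (−0.37) and the adaptor gene Pik3ap1 (−0.25). Naive and memory B cell genes had a median of −0.11, with 14 of 19 negative (camera adjusted p = 0.0024; adjusted p = 0.25 with an estimated correlation). Adjusted over the list alone 5 fell and 1 rose; Ms4a1, which encodes CD20, gave −0.25. This call was lost with a term for sex and with the male libraries alone, which share the median of −0.15 by design. Without wild-type library 1 the median was −0.17.

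Interferon-γ targets had a median of −0.14, with 17 of 21 negative (camera adjusted p = 0.0080; adjusted p = 0.527 with an estimated correlation). Their leading genes went apart, Ciita at −0.22 and Cxcl10 at 0.65. G2/M genes had a median of −0.05, with 25 of 34 negative (camera adjusted p = 0.013; adjusted p = 0.148 with an estimated correlation), Kif23 at −0.19 and Nusap1 at −0.17. Replication histone genes had a median of −0.39, with 16 of 19 negative (camera adjusted p = 0.0018; adjusted p = 0.527 with an estimated correlation), Hist1h1a at −0.63 and Hist1h3e at −0.73. In these 3 lists 0 genes passed limma's test adjusted over the list alone, and 2, 2 and 1 had an unadjusted p under 0.05. Without Tbk1-deficient library 1 the camera adjusted p was 0.067 for interferon-γ targets (median −0.12) and 0.053 for G2/M genes (−0.05). Without Tbk1-deficient library 4 it was 0.194 for interferon-γ targets (median −0.07). Without wild-type library 4 it was 0.245 for replication histones (median −0.14; −0.25 without Tbk1-deficient library 3), whose score in that library was 1.01 against −0.25 to 0.12 in the other wild-type libraries. Over all alternatives the adjusted p ranged from 7.68e-05 to 0.527 for interferon-γ targets, from 0.0035 to 0.148 for G2/M genes and from 2.77e-05 to 0.527 for replication histones. The call on interferon-γ targets was also lost with a term for sex and with the male libraries alone (median −0.12, shared by design). That on G2/M genes was lost after rescaling every library to the same sum (−0.04) and with the male libraries alone (−0.06).

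The erythroid list was lower, with all 11 tested genes negative and a median of −0.28 (camera adjusted p = 2.47e-05; adjusted p = 0.074 with an estimated correlation). Of the 11 genes, 4 fell adjusted over the list alone. The median was −0.16 with no filter and −0.42 with a filter at a mean of 5 FPKM. Hba-a1 stood at 218 ± 18.7 against 340 ± 66.2 FPKM (−0.62, limma adjusted p = 0.092) and Car2 at 14.8 ± 0.836 against 18.7 ± 0.695 (−0.32, limma adjusted p = 0.067). Of the 22 alternatives Hba-a1 passed in 4, among them the male libraries alone (−0.80, limma adjusted p = 0.013), and not in 18. The myeloid list gave a median of −0.20 over 7 tested genes (camera adjusted p = 0.314), and was called lower with a term for sex, with the male libraries alone and with no filter. None of these calls held with an estimated correlation (adjusted p = 0.439 with a term for sex and 0.545 with the male libraries alone). Of the T cell list, Cd3e, named after its values were seen, stayed at 0.197 FPKM or less in every library, while Cd2 gave −0.39 and Lat −0.11. Of the NK list, Il2rb gave 0.18 and Prf1 −0.25. Of the dendritic cell list, Bst2 gave 0.09 and Flt3 −0.09. None of the platelet genes reached the filter (list means of 0.0464 against 0.165 FPKM); with no filter the platelet list was called lower, though not with an estimated correlation.

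**Figure D3:**
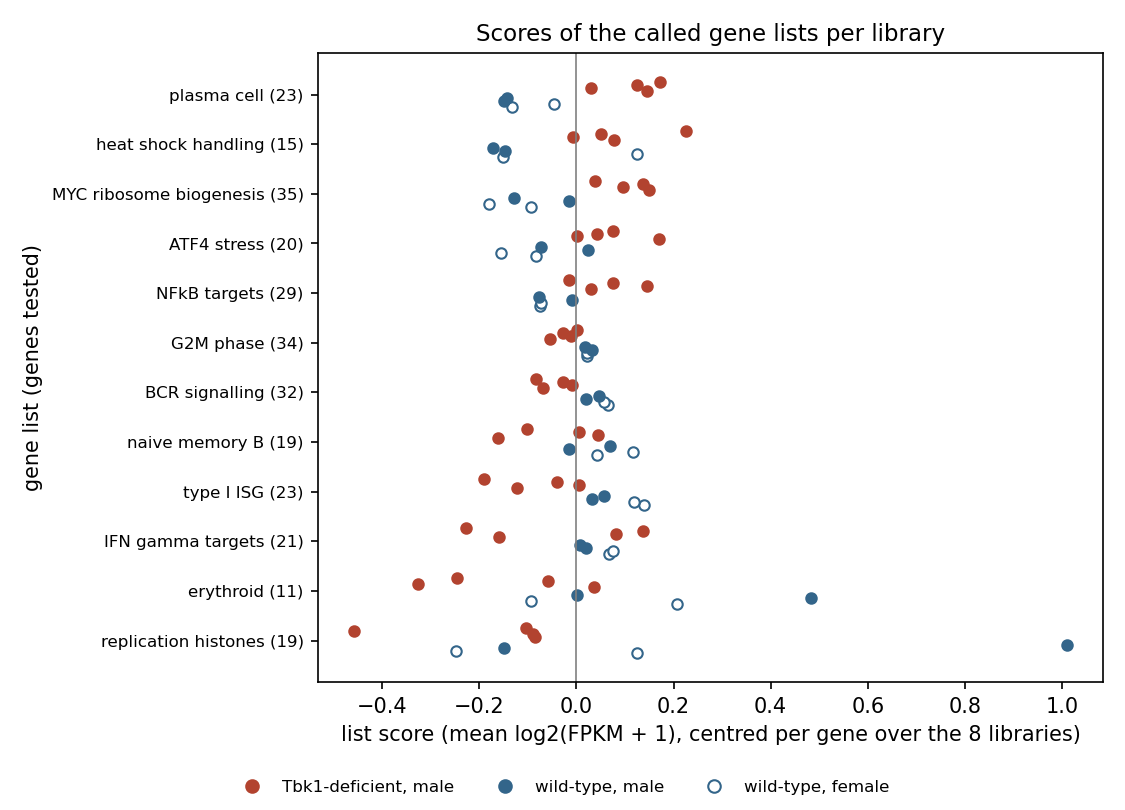
Score of each of the 12 called gene lists in each library: the mean over the list of log2(FPKM + 1), centred per gene over the 8 libraries. The number of genes tested is in brackets, and open points are female libraries. Scores of the MYC and ribosome biogenesis list run from 0.04 to 0.15 in the Tbk1-deficient libraries and from −0.18 to −0.02 in the wild-type libraries, while the scores of several other lists overlap.

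The remaining lists were not called. The germinal centre list had a median of −0.05 and a mean of 0.0035, which differ in sign (29 genes, camera adjusted p = 0.442). Rgs13 was its 1 gene that rose over all genes; adjusted over the list alone 1 rose and 1 fell. Medians were −0.11 for T-bet-associated B cell genes (Fcrl5 0.58, Cd80 0.42), of which 3 rose adjusted over the list alone, and −0.07 for immediate early genes (Egr2 −0.46). T cell interaction genes had a median of −0.11, and Il10 rose over all genes. FOXO1 targets had a median of −0.08, and Tsc22d3 fell over all genes. Medians were −0.05 for autophagy and lysosome genes, −0.04 for migration and adhesion genes (Cnr2 −0.29) and −0.04 for glycolysis genes (Hk2 0.60, Aldoc −0.52). The list of TBK1 partners and upstream sensors had a median of −0.02 (Optn 0.27, Tlr9 −0.19, camera adjusted p = 0.407), which was 0.0012 after rescaling every library to the same sum. Ribosomal protein genes had a median of −0.04 (0.0043 after quantile normalization), with Rpl30 at 0.23. S-phase genes (0.0021) and p53 targets (0.00056, with Bbc3 at 0.42 and Cdkn1a at 0.50) had medians that turned negative under median-ratio scaling (−0.0044 and −0.0057). BCL2-family genes (0.0082), oxidative phosphorylation genes (0.02, Ndufa1 −0.24) and cholesterol synthesis genes (0.03) also lay near 0. With a term for sex the oxidative phosphorylation and cholesterol synthesis lists had medians of −0.08 and −0.07 and were called lower, though not with an estimated correlation (adjusted p = 0.80 for both). The autophagy, T cell interaction and ribosomal protein lists were called lower under some alternatives, these including the term for sex, and not with an estimated correlation. Leaving out 1 library also brought calls, none of which held with an estimated correlation. Without Tbk1-deficient library 1, glycolysis (median −0.14), ribosomal protein (−0.10) and autophagy genes (−0.05) were called lower. T cell interaction genes were called lower without Tbk1-deficient library 2 (−0.13), Tbk1-deficient library 3 (−0.13) or wild-type library 2 (−0.09). FOXO1 targets were called lower without Tbk1-deficient library 3 (−0.10) or wild-type library 3 (−0.11), and oxidative phosphorylation genes higher (0.06 and 0.06). Cholesterol synthesis genes were called higher without wild-type library 3 (0.10) but lower without wild-type library 2 (−0.07). Ribosomal protein genes were called lower without wild-type library 2 (−0.10) but higher without Tbk1-deficient library 3 (0.04). Autophagy genes were called lower without wild-type library 2 (−0.05).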

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

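The tests of a general fall of B cell genes, of DNA around the Cre insertion and of the other splits of the libraries for the MYC and erythroid lists, and the sex term, were chosen only after the result was seen. Chance makes about 1 in 20 groups of 4 hold a library far from the others, and 11 of 232 groups did, against 11.6 expected. A library stood far from the other 3 of its genotype for Snhg9 (11.9 FPKM in wild-type library 3, others 5.22 to 5.81), Hvcn1 (99.3 in wild-type library 2, others 109 to 111), Irf4 (14.0 in wild-type library 2, others 10.3 to 10.8), Kif23 (46.5 in Tbk1-deficient library 1, others 53.4 to 54.8) and S100a9 (3.24 in Tbk1-deficient library 2, others 0 to 0.247). Among list scores the same held in wild-type library 2 for plasma cell genes (−0.046), T-bet-associated genes (−0.13), immediate early genes (0.076) and heat shock genes (0.13). It held in wild-type library 3 for NF-κB targets (−0.0094) and in Tbk1-deficient library 3 for replication histones (−0.46). Of the genes below the filter, 2 passed limma when no filter was set. Psors1c2 (log2 fold change 0.16) was listed at 0 in every wild-type library and at 0.113 to 0.131 FPKM in the Tbk1-deficient libraries, about 1 fragment each. Slc1a3 (0.49) had means of 0.654 against 0.176 FPKM.

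The 38 changed genes exceeded what other splits gave. Of the 35 splits of the 8 libraries into 4 against 4, 1 (the real one) gave as many, and the highest other gave 2. As 1 of 35 is the smallest share this test can give, chance is made unlikely but not excluded. The 12 called lists did not exceed the other splits: 10 of the 35 splits gave as many, the highest 16.

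Genes of MYC targets and ribosome biogenesis were higher, and 1 of the 35 splits (the real one) gave a median as large as 0.20 (highest other 0.16). The list was picked for this test from 28 after its result was seen, so chance is not excluded for it. With a term for sex the median was 0.17, which argues against sex as the whole cause of its size. The evidence for the list was weaker with that term. Fry gave adjusted p = 0.101 (0.013 without the term), and camera with an estimated correlation 0.439 (0.075 without it). The median was 0.2027 after removal of the trend on GC content and transcript length, and 0.198 at the lowest of 3 other scalings, against these as causes. What stays open, untested, is loss of TBK1, the presence of Cre, cell composition and cell handling. The heat shock list, fixed as a marker of handling, was also higher (median 0.21) and shares Hspe1 and Hspd1. In each genotype, though, the library with the highest heat shock score had the lowest MYC list score. These were Tbk1-deficient library 4 (0.23 and 0.04) and wild-type library 2 (0.13 and −0.18).

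Erythroid transcripts were lower, and 1 of the 35 splits (the real one) gave a median as large in size as 0.28 (highest other 0.23), but this list too was picked from 28 after its result was seen, so chance is not excluded for it. The median was −0.32 with a term for sex, which argues against sex as the whole cause. The sort was gated on B220-positive, GL7-positive cells; if fewer erythroid cells or less free RNA that passed it were the cause, the globin score would follow the other erythroid genes within genotypes. The correlation was −0.020 (exact permutation p = 0.988), but ranged from −0.27 to 0.23 on leaving out each library, so less erythroid RNA cannot be told apart from other causes with 8 libraries. A biological difference of the mice, such as anaemia or parasite load, was not tested.

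Cd79a was lower by −1.26, while the other B cell receptor signalling genes had a median of −0.081, which argues against a general fall of these genes as the cause. Within 10 Mb of Cd79a, 2 of 178 genes changed (Nfkbid and Vasp, the latter named after its values were seen) against 35 of 9343 elsewhere (Fisher's exact p = 0.152), so DNA carried along with the Cre insertion cannot be told apart from chance for these neighbours. Bcl3 (0.52) and Bbc3 (0.42) also lie within 10 Mb of Cd79a. They did not pass limma's test over all genes, and the same limit holds for them. A candidate explanation is the loss of 1 working Cd79a allele to the insertion, a hypothesis that this series, without a group of Cre alone, does not test.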

How the results depend on the processing

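The term for sex, the male libraries alone and the exclusion of transcripts under 300 nt were chosen after seeing the data; the cause of each change below was not tested unless fewer genes or libraries account for it. Cd79a, Fscn1 and Rgs13 passed in all 22 alternatives, Cd79a between −1.43 and −1.18 (adjusted p from 7.14e-06 to 0.039), and Tbk1 in none (−0.32 to −0.19, adjusted p from 0.154 to 0.687). The changed, higher and lower genes numbered 12, 9 and 3 with no filter, where 15256 genes were tested and the intensity trend was refitted. They numbered 20, 14 and 6 after rescaling to the same sum, 220, 122 and 98 with array weights, and 12, 8 and 4 with a term for sex. With the male libraries alone they numbered 20, 14 and 6 (fewer libraries), and with a filter at a mean of 5 FPKM 15 were higher. With the replicate number as a block they numbered 4, 3 and 1; the numbers do not pair the libraries, since 0 libraries correlated best with their own number (correlations −0.14, −0.01, −0.22 and −0.06 for numbers 1 to 4). Leaving out each library gave 5 to 117 changed, 4 to 63 higher and 1 to 54 lower. Camera with an estimated correlation called 0 lists, and 0 in each other setting too. With a filter at a mean of 5 FPKM, too few replication histone genes were left to test that list. Fry called 6, but 3 with quantile normalization, 2 after rescaling, 2 with a term for sex, 2 with the male libraries alone, 0 with the replicate block, and on leaving out Tbk1-deficient libraries 1 to 4 gave 5, 5, 4 and 5 and wild-type libraries 1 to 4 gave 3, 5, 4 and 4. The sign turned for p53 targets (−0.047) at a mean of 5 FPKM; for S-phase genes (−0.0044) and p53 targets (−0.0057) under median-ratio scaling; for S-phase genes (−0.00060), p53 targets (−0.0062) and ribosomal proteins (0.0043) under quantile normalization; and for TBK1 partners (0.0012) after rescaling. With array weights it turned for oxidative phosphorylation (−0.026), cholesterol synthesis (−0.045), BCL2-family genes (−0.0078), Bach2 (0.023), Irf8 (−0.0071) and Pax5 (0.013). A term for sex and the male libraries alone give the same fold changes by design. In both the sign turned for FOXO1 targets (0.026), oxidative phosphorylation (−0.076), cholesterol synthesis (−0.069), S-phase genes (−0.014), BCL2-family genes (−0.0089), Bach2 (0.14), Irf8 (−0.0096) and Pax5 (0.081). Leaving out each library in turn gave ranges that span 0 for oxidative phosphorylation (−0.041 to 0.059), cholesterol synthesis (−0.072 to 0.099), S-phase genes (−0.0082 to 0.031), germinal centre genes (−0.061 to 0.011), glycolysis genes (−0.137 to 0.029), BCL2-family genes (−0.011 to 0.021), p53 targets (−0.0215 to 0.044), ribosomal proteins (−0.103 to 0.041), TBK1 partners (−0.038 to 0.0025), Bach2 (−0.139 to 0.044), Irf8 (−0.0082 to 0.025), Pax5 (−0.114 to 0.030) and Lat (−0.35 to 0.072). Of the comparisons of a list or named gene with its reported value, 2181 kept direction and side of the threshold, 227 kept direction but no longer passed, 73 kept direction and passed newly, and 60 changed sign. Pseudocounts of 0.1 and 0.25 gave 38 changed genes, no intensity trend 34, the robust variance step 47 and the exclusion of short transcripts 41. The filter at a mean of 1 FPKM, rather than depth, leaves genes below it untested. About 1 fragment per library stood behind the lowest values, and few may stand behind the short transcripts Snhg9 and Snora81.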

Other observations

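Across libraries the 1st principal component held a larger share of the variance than the 2nd (18.0%). The 2nd separated the genotypes, and wild-type library 2, which is female, lay at the far end of the 1st (22.4).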
